A study of Mus musculus with 8 samples.

How the data were processed

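RNA was taken from olfactory epithelium dissected from C57BL/6J mice aged 40 weeks, and libraries were made with a stranded, poly(A)-selecting kit and sequenced as paired reads, per the labels' protocols. The series' design text speaks of olfactory sensory neurons, while the protocol describes dissected epithelium, which holds other cells too. Samples were grouped by their titles, 4 libraries titled IGF1R_flfl and 4 titled OMP_IGF1R. The genotype field gives each title group the name of the other, and no genotype was inferred from the values. The numbers that open the titles, which are not the replicate numbers, fall in separate ranges (35138 to 35141 for IGF1R_flfl and 35156 to 35159 for OMP_IGF1R), so any batch that follows those numbers cannot be separated from the group.

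The deposited table of read counts holds whole-number counts per gene and library, not normalized, as its values show. Reads were processed with Trim Galore 0.3.7, TopHat2 2.0.14, SAMtools 1.2 and DESeq2 (version not given in the sources used here) on GRCm38 (mm10), per the submitters' processing notes. The counting step, its strand setting and whether reads or fragments were counted are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies such as olfactory receptors may therefore share reads. The authors' deposited table of their comparison holds a mean normalized signal per gene, log2 fold changes with standard errors, a test score, and p-values with adjusted p-values, per the file headers. These authors' values were used for description alone.

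The files held 25913 genes. Description text attached to 23 gene identifiers was trimmed, and 25012 identifiers matched the reference gene table, whose symbols helped to find list members. Gene symbols and coordinates are those of the deposited file. Replicates were compared before averaging: within-group pairs differed by a mean chi-square per gene of 11.9 to 108.9, far above sampling noise, so no library was counted as a copy of another.

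Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the 17381 genes that passed the filter and a threshold of 0.05. CPM values use TMM effective library sizes. Total counts of 18802471 to 27793375 per library set the depth, and genes of low expression rest on few reads, so their fold changes are less certain than those of abundant genes. Floors cover counting error only.

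Before the data were examined, 46 gene lists of pathways and of cell types that the dissection can hold were fixed, with the groups, the tests and the alternatives. List members were counted as higher or lower at an adjusted p under 0.05 over all genes and adjusted over the list alone. The 45 lists with at least 5 tested members were tested with camera (limma 3.58.1) on logCPM with a prior count of 2 and an inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. By camera 23 lists were called, 17 higher and 6 lower. With an estimated correlation camera called 0 lists, 5 had an unadjusted p under 0.05, and fry called 8. The 8 were the mature neuron, odour transduction and activity-linked lists, lower, and the immature neuron, precursor, cell cycle, horizontal basal and microvillar lists, higher. Fry asks whether a list moves on balance and does not compare it with other genes. Summed CPM of each list were compared with exact two-sided permutation tests, for which 4 against 4 libraries give 70 arrangements and a smallest p of 0.0286, and 11 lists reached it, each at an adjusted p of 0.119.

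The named genes were Igf1r, Omp, Insr and Igf1, the 12 higher and 12 lower genes with the largest absolute log2 fold change among called genes with a symbol, a mean logCPM of at least 1 and no overlap between the groups (1280 genes passed), and up to 4 members with the smallest p of each list discussed. Genes outside this rule are said to have been chosen after their values were seen. A list member withheld for evaluation is not reported here.

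Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, scaling to the mature neuron list without Omp, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with sample weights, leaving out each library, windows of 5 and 20 Mb, receptors with at least 10 reads on average, raw library totals and the mean logCPM of list members. Leaving out IGF1R_flfl 2 and OMP_IGF1R 17 together was chosen after seeing the data. The tests were tried on simulated data for the comparison of OMP_IGF1R with IGF1R_flfl, 17381 genes of which 200 were changed. EdgeR recovered 43.1% of genes changed by 0.5 and 74.4% of genes changed by 1 on the log2 scale, and 4.20% of its calls were false. DESeq2 recovered 59.1% and 82.2%, and 21.9% of its calls were false.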

Results

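Gene expression was measured by stranded, poly(A)-selected RNA sequencing of olfactory epithelium dissected from C57BL/6J mice aged 40 weeks. The study asked how removal of the insulin-like growth factor 1 receptor, Igf1r, from olfactory sensory neurons affects their RNA, with 4 libraries per group. The 2 groups are named here by the library titles, IGF1R_flfl (replicates 1, 2, 13 and 3) and OMP_IGF1R (replicates 11, 12, 17 and 18). The genotype field gives the opposite names: libraries titled IGF1R_flfl carry a knockout genotype and libraries titled OMP_IGF1R carry a control genotype. Each fold change below is therefore of the libraries titled OMP_IGF1R over those titled IGF1R_flfl, and the direction with respect to genotype depends on which label is right. Total counts were 27793375, 26769644, 23176815 and 25789177 in IGF1R_flfl 1, 2, 13 and 3, and 18802471, 25585192, 22810982 and 25393685 in OMP_IGF1R 11, 12, 17 and 18. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

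The targeted gene and the gene that names the driver were both lower in the libraries titled OMP_IGF1R. Igf1r (ENSMUSG00000005533, GRCm38 chromosome 7, 67952859 to 68226780), the receptor of insulin-like growth factors, stood at 72.9, 55.5, 67.9 and 69.9 CPM in IGF1R_flfl 1, 2, 13 and 3 and at 49.6, 43.9, 34.5 and 40.5 CPM in OMP_IGF1R 11, 12, 17 and 18. The means were 66.5 ± 7.65 and 42.1 ± 6.32 CPM (SD, n = 4 each), a log2 fold change of -0.66 (SE 0.116, edgeR adjusted p = 0.0117). Omp (ENSMUSG00000074006, chromosome 7, 98143360 to 98145502), a protein of mature olfactory sensory neurons, stood at 5475, 4470, 4864 and 6734 CPM in the libraries titled IGF1R_flfl and at 2123, 1708, 2185 and 1861 CPM in those titled OMP_IGF1R, a log2 fold change of -1.45 (SE 0.132, edgeR adjusted p = 0.00179). Both genes were thus lower in the 4 libraries whose genotype field names the control. Counts over the whole gene include exons outside any deleted part of Igf1r and other cell types of the epithelium, so they do not measure the deletion itself. With libraries scaled to the other mature neuron genes, the Igf1r difference was -0.12 (SE 0.130, edgeR adjusted p = 0.41) and its call was lost, while Omp stayed lower by a log2 fold change of -0.91 (SE 0.0803, edgeR adjusted p = 0.000192).

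**Figure D1:**
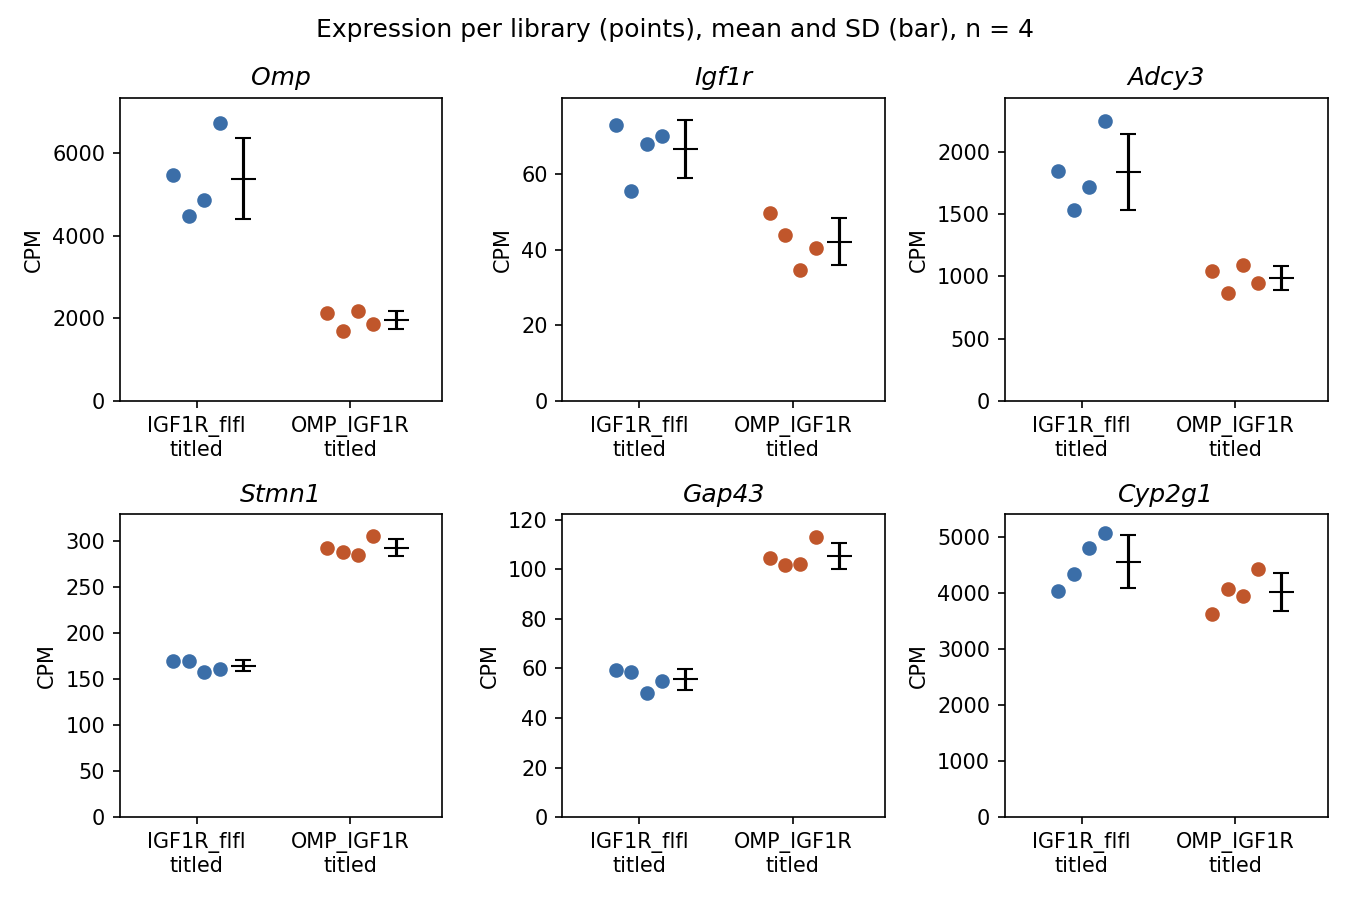
Expression in CPM, normalised counts scaled to library size (vertical axes), of 6 genes in each library (points), with the mean and SD of the 4 libraries of each title group (bars). Omp, Igf1r and Adcy3 were lower and Stmn1 and Gap43 higher in every library titled OMP_IGF1R, while Cyp2g1, chosen after its values were seen, overlapped between the groups; scaled to mature neuron genes, the Igf1r difference was -0.12 on the log2 scale and no longer called.

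Across the 17381 genes tested, 1425 changed between the groups at an edgeR adjusted p under 0.05. Of these, 492 were higher and 933 lower in the libraries titled OMP_IGF1R, so 34.5% of the calls were higher. The changes were mostly small, with a median absolute log2 fold change of 0.50 among the called genes, and 189 genes changed at least 2-fold (75 higher, 114 lower). The groups did not overlap for 2934 of the 17381 tested genes, where chance gives 2.86% of genes on average. Genes can move together, so that share can vary widely. Among the 1425 called genes the groups did not overlap for 1403, but calling itself favours separated groups, so chance gives no measure there. The count fell to 841 without IGF1R_flfl 1, 886 without IGF1R_flfl 3, 724 without OMP_IGF1R 11, 613 without OMP_IGF1R 12 and 569 without OMP_IGF1R 18. Scaled to mature neuron genes, which moved the median log2 fold change of all genes from -0.012 to 0.52, 13145 genes were called and 99.0% of them were higher, so a change of sign under it says little of a single gene or list.

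Genes of mature olfactory sensory neurons were lower in the libraries titled OMP_IGF1R. Of the 29 tested members of the mature neuron list, 21 fell, 1 rose and 7 did not pass the test, with a median log2 fold change of -0.53. Besides Omp, the members with the smallest p included Slc17a6 (-0.50), a vesicular glutamate transporter, Pde1c (-0.77), a phosphodiesterase, and Syt1 (-0.53), a calcium sensor of synaptic vesicles. The member that rose was Calb2 (0.50), a calcium-binding protein that was singled out after its values were seen. In the overlapping list of odour transduction genes, 16 of 25 members fell and 0 rose, with a median of -0.51. Adcy3, the adenylyl cyclase of odour signalling, fell from 1835 ± 302 to 987 ± 97.2 CPM (SD, n = 4 each), and Ano2, a calcium-activated chloride channel, changed by -0.90. Adjusted over the list alone, 26 mature neuron genes were lower and 1 higher, and 19 transduction genes were lower. Both lists were lower by camera (adjusted p = 7.59e-16 and 9.61e-12), and the calls were lost at an adjusted p = 0.39 for each list with an estimated correlation. Scaling to mature neuron genes sets this list near 0 by construction (median 0.00188, with Slc17a6 at 0.027 and Syt1 at 0.00188, and 0.022 for the overlapping transduction list) and moves the median of all genes from -0.012 to 0.52, so it does not test whether these lists fell. The library IGF1R_flfl 2 stood apart in olfactory bulb and oligodendrocyte genes, and without it 24 mature neuron genes were lower.

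Olfactory receptor genes were lower on balance. Each sensory neuron expresses mainly 1 receptor, so their RNA follows which neurons are present. Of 875 receptors tested, 122 fell and 5 rose, and 76.2% had a negative fold change (median log2 -0.33). Adjusted over the list alone, 150 fell and 5 rose. The share called lower was 13.9% among receptors and 4.91% among other genes (Fisher's exact test, two-sided, odds ratio 3.14, p = 5.93e-23), with genes counted as if independent. Their summed expression was 3145 ± 288 CPM in the libraries titled IGF1R_flfl and 2217 ± 149 CPM in those titled OMP_IGF1R, a ratio of 0.705, with no overlap (exact permutation test, two-sided, n = 4 each, p = 0.0286, the smallest possible, adjusted p = 0.119 over the lists). Among the receptors with the largest falls were Olfr175-ps1 (log2 -2.88), Olfr297 (-2.46) and Olfr1299 (-2.27), and the abundant Olfr1507 fell from 205 ± 92.3 to 57.5 ± 17.3 CPM. The 5 that rose, named after their values were seen, were Olfr1535 (1.83), Olfr357 (1.65), Olfr56 (0.91), Olfr420 (1.98) and Olfr94 (1.34), of which Olfr56 alone averaged above 2 CPM in either group. Near-identical receptors may share reads, so single receptors are uncertain. The called number was 82 without IGF1R_flfl 13, 76 without IGF1R_flfl 3 and 62 without OMP_IGF1R 11. It was 54 without OMP_IGF1R 12 and 84 without OMP_IGF1R 18. The receptor list was called by camera (adjusted p = 6.18e-10) but not with an estimated correlation (adjusted p = 0.40). Under the scaling to mature neuron genes its median was 0.20, with 97 receptors higher and 58 lower. That change of sign follows from the shift of all genes (median 0.52). Camera under it placed the list lower than other genes (adjusted p = 1.18e-78). The scaling moves all genes and is set by genes of the same neurons, so this is no separate support.

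Genes of immature neurons, of their precursors and of dividing cells were higher in the libraries titled OMP_IGF1R. Of the 25 immature neuron genes, 11 rose and 1 fell (median log2 0.26). Stmn1, a regulator of microtubules, rose from 165 ± 6.25 to 292 ± 9.27 CPM and Gap43, a growth cone protein, from 55.7 ± 4.21 to 105 ± 5.37 CPM (SD, n = 4 each; edgeR adjusted p = 0.000778 and 0.000881). The transcription factors Nhlh1 and Nhlh2 each changed by 1.10, and the member that fell, named after its values were seen, was Stmn4 (-0.74). In the list of basal progenitors and neuronal precursors, 14 of 18 members rose and 0 fell (median 0.63), among them the transcription factors Insm1 (1.08), Neurod1 (1.03) and Sox11 (0.87) and the histone methyltransferase Ezh2 (0.57). In the cell cycle list, 28 of 37 members rose and 0 fell (median 0.63), among them Cdk1 (0.94), Top2a (0.93), Tpx2 (0.86) and the proliferation marker Mki67 (0.88). Adjusted over the list alone, the numbers that rose were 12, 15 and 32, and 1 immature neuron gene fell. Summed expression was 318 ± 14.9 and 462 ± 5.51 CPM for cell cycle and 621 ± 53.5 and 796 ± 43.5 CPM for precursor genes, each with no overlap (exact permutation test, two-sided, n = 4 each, p = 0.0286, adjusted p = 0.119), and 3927 ± 390 and 4356 ± 161 CPM for immature neuron genes, with overlap (exact permutation test, two-sided, n = 4 each, p = 0.0857, adjusted p = 0.246). Camera gave adjusted p = 2.05e-08, 1.77e-14 and 5.37e-26 for the 3 lists, and the calls were lost with an estimated correlation (adjusted p = 0.30, 0.30 and 0.21). Without IGF1R_flfl 2 and OMP_IGF1R 17, which stood apart in bulb and muscle genes, 12 immature neuron, 14 precursor and 23 cell cycle genes rose.

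**Figure D2:**
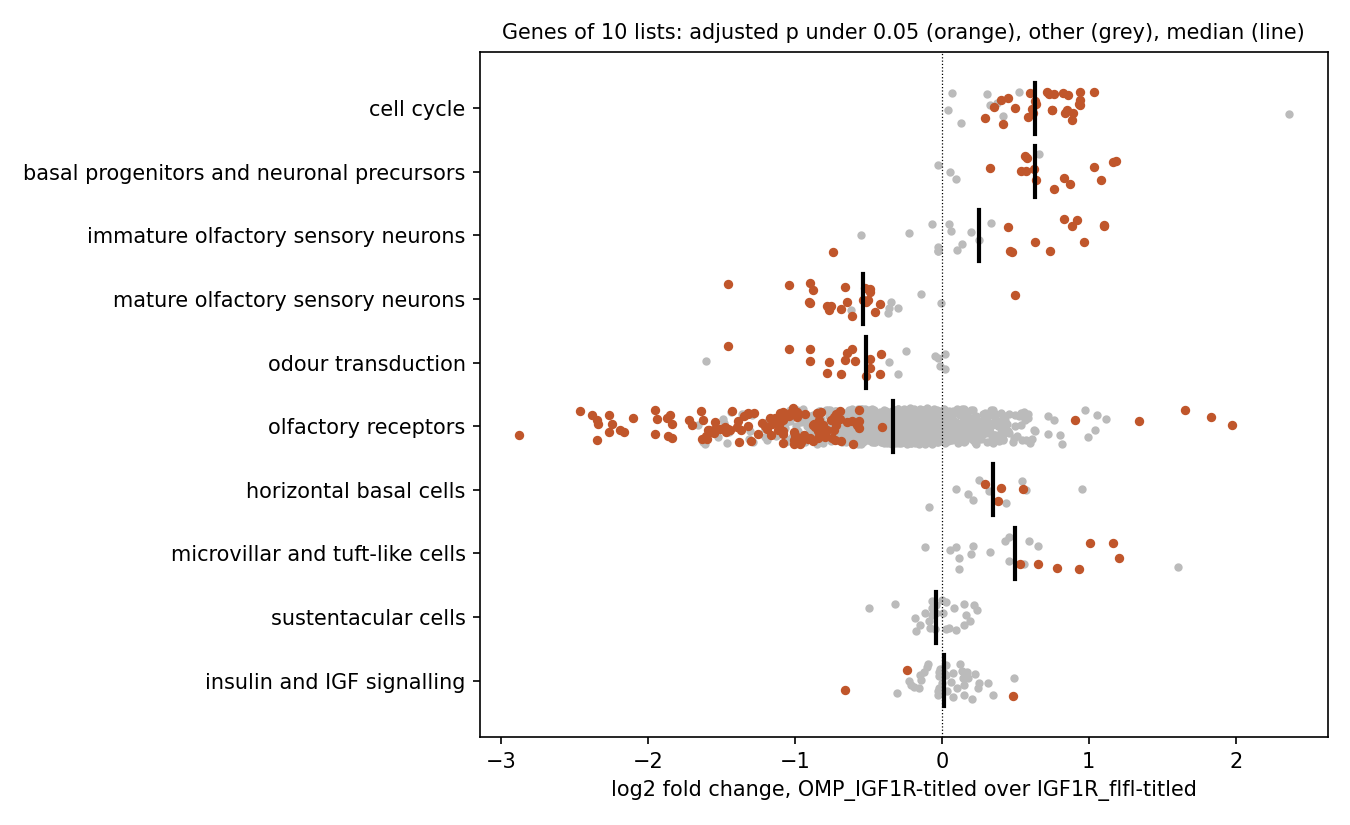
Log2 fold change of the libraries titled OMP_IGF1R over those titled IGF1R_flfl (horizontal axis) for the tested genes of 10 lists, with called genes in orange, other genes in grey and the list median as a line; vertical scatter within a list has no meaning. Medians were 0.63 for cell cycle genes, -0.53 for mature neuron genes and -0.04 for sustentacular cell genes; scaled to mature neuron genes, the medians of the mature neuron list, set near 0 by that scaling, and of the odour transduction, receptor and sustentacular lists changed sign.

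Of 27 genes of sustentacular cells, the supporting cells of the epithelium, 0 were called by edgeR (median log2 -0.04, camera adjusted p = 0.97), and scaled to mature neuron genes the median changed sign to 0.51. At an unadjusted p under 0.05 there were 5, DESeq2 called 3 and voom 0, and Cyp2g1, a cytochrome P450 of these cells chosen after its values were seen, stood at 4568 ± 469 and 4029 ± 337 CPM. Of 28 gland genes, 0 were called by edgeR, DESeq2 or voom (median -0.02, camera adjusted p = 0.0823) and 7 had an unadjusted edgeR p under 0.05. The glands' median was negative while camera placed the list on the higher side, and its sign depended on the settings (-0.68 to 0.39 over the libraries left out). Summed gland genes varied widely within the groups. They ran from 30659 CPM in IGF1R_flfl 3 to 73230 CPM in IGF1R_flfl 13, and from 42099 CPM in OMP_IGF1R 11 to 63975 CPM in OMP_IGF1R 17. Among the genes of horizontal basal cells, the reserve stem cells of the epithelium, 4 of 14 rose and 0 fell (median 0.35): Itgb4 (0.29), Dsc3 (0.55), Lamb3 (0.40) and Krt17 (0.38), which encode adhesion, matrix and keratin proteins. Adjusted over the list alone, 8 rose, and without IGF1R_flfl 2 and OMP_IGF1R 17 there were 3 higher genes. Their summed expression was 516 ± 39.1 and 688 ± 118 CPM, with no overlap (exact permutation test, two-sided, n = 4 each, p = 0.0286, adjusted p = 0.119), and was highest in OMP_IGF1R 17 (862 CPM, against 598 to 652 CPM in the others of its group). Itgb4 lost its call without OMP_IGF1R 18 (adjusted p = 0.0619), Dsc3 without IGF1R_flfl 1 or OMP_IGF1R 12 or 18 (up to 0.0659), Lamb3 without IGF1R_flfl 1 or OMP_IGF1R 11 or 18 (up to 0.0704) and Krt17 without any library but IGF1R_flfl 3 (up to 0.102). Camera called this list (adjusted p = 9.36e-05), and the call was lost with an estimated correlation (adjusted p = 0.39) and under the scaling to mature neuron genes (adjusted p = 0.0537).

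Material of neighbouring tissue was seen in single libraries. Olfactory bulb and oligodendrocyte genes summed to 2825 CPM in IGF1R_flfl 2 and to 985 to 1099 CPM in the other libraries. Skeletal muscle genes summed to 403 CPM in OMP_IGF1R 17 and to 19.97 to 27.2 CPM in the others, and their median log2 fold change of 2.90 came with 0 of 10 members called by edgeR over all genes (0 by DESeq2 or voom, 7 at an unadjusted p under 0.05) and 7 adjusted over the list alone. Camera called the muscle list (adjusted p = 0.0235, adjusted p = 0.70 with an estimated correlation and adjusted p = 0.37 under the scaling to mature neuron genes) but not the bulb list (adjusted p = 0.116), in which Eomes, a transcription factor of bulb projection neurons, fell (-0.49). The call of Eomes was lost without any 1 library but IGF1R_flfl 2 or OMP_IGF1R 17 (adjusted p up to 0.104), and its sign changed to 0.040 with libraries scaled to mature neuron genes. Leaving out both libraries gave 1297 called genes (456 higher, 841 lower).

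**Figure D3:**
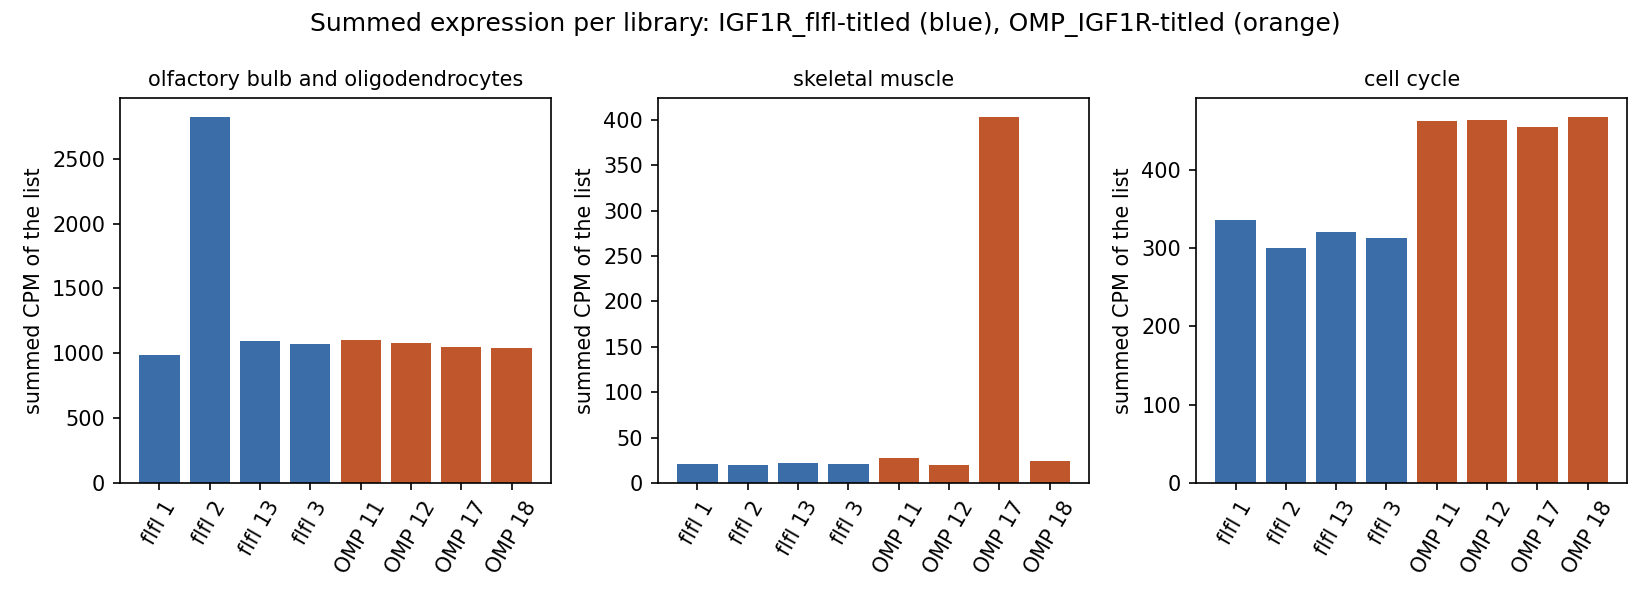
Summed expression in CPM (vertical axes) of olfactory bulb and oligodendrocyte genes, skeletal muscle genes and cell cycle genes in each library (1 bar per library, blue for titles IGF1R_flfl and orange for OMP_IGF1R). The bulb sum stood at 2825 CPM in IGF1R_flfl 2 and the muscle sum at 403 CPM in OMP_IGF1R 17, while cell cycle sums separated the groups.

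Chi3l4, a chitinase-like protein, had the largest rise among the genes that met the rule for naming. It was at 14.1 ± 22.9 CPM in the libraries titled IGF1R_flfl and at 890 ± 573 CPM in those titled OMP_IGF1R (log2 6.00, SE 1.32, edgeR adjusted p = 0.0255; 5.59 to 8.37 over the libraries left out, the highest without IGF1R_flfl 13), and its paralog Chi3l3 rose by 2.31. Fcgbp, a mucus protein, rose from 23.5 ± 12.5 to 191 ± 91.9 CPM, and the predicted gene Gm10935, which lies within the bounds of Fcgbp, rose by 3.40. The other rises were in Spink5 (2.08), a protease inhibitor, Myot (1.99), a muscle protein, AF529169 (1.97), Alox12e (1.70), a lipoxygenase, Gm8113 (1.45), Clca2 (1.40), C3 (1.31), a complement component, and Mx1 (1.21), an interferon-induced GTPase. The 12 largest falls were in 11 olfactory receptor genes and Twist2, a transcription factor that fell from 5.90 ± 0.853 to 1.71 ± 0.298 CPM (log2 -1.79). The receptors not yet given were Olfr183 (-2.10), Olfr725 (-1.93), Olfr914 (-1.86), Olfr173 (-1.83), Olfr1193 (-1.70), Olfr46 (-1.64) and Olfr1442 (-1.63). Within their groups, IGF1R_flfl 13 stood apart in Chi3l4 and Fcgbp (48.2 and 42.1 CPM) and OMP_IGF1R 17 in Myot and Clca2 (7.61 and 19.6 CPM). Reads may be shared between Chi3l3 and Chi3l4, between Fcgbp and Gm10935 or between receptors, so these genes are uncertain. Of the 26 called genes named by size or design, 19 kept their call in all 8 fits that left out 1 library. Alox12e lost it without IGF1R_flfl 1 (adjusted p = 0.0524), Olfr46 without OMP_IGF1R 12 (0.0593), and Chi3l4 and Mx1 without IGF1R_flfl 1 or 3 or OMP_IGF1R 12 or 18 (up to 0.0668 and 0.0723). Chi3l3 lost it without the same libraries or IGF1R_flfl 13 (up to 0.0852), Myot without any library but OMP_IGF1R 12 or 17 (up to 0.108) and Olfr1442 without any but IGF1R_flfl 2 or OMP_IGF1R 18 (up to 0.0945).

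Of the 45 tested genes of insulin and IGF signalling, 1 rose and 2 fell: Igfbp2 (0.48), an IGF-binding protein, rose, and Igf1r and Foxo3 (-0.23), a transcription factor inhibited by the pathway, fell. The call of Foxo3 was lost without any 1 library but IGF1R_flfl 13, with an adjusted p of up to 0.139, and scaled to mature neuron genes its sign changed (0.30). Insr, the insulin receptor, stood at 139 ± 4.30 and 140 ± 9.80 CPM (log2 0.02, SE 0.0603, edgeR adjusted p = 0.90), and Igf1, the ligand, at 9.41 ± 3.10 and 10.4 ± 0.768 CPM (0.15, SE 0.218, edgeR adjusted p = 0.73). Adjusted over the list alone, 1 rose and 1 fell, and the list was not called by camera (adjusted p = 0.38).

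Genes close to Omp and Igf1r were examined because a targeted allele can carry flanking sequence of another strain. On chromosome 7, leaving out Omp and Igf1r, 102 of 1428 tested genes were called (7.14%, against 8.28% elsewhere; Fisher's exact test, two-sided, p = 0.144). Within 10 Mb of either gene, 28 of 328 were called (8.54%, against 8.18%; Fisher's exact test, two-sided, p = 0.76). The window count was 14 without OMP_IGF1R 11 and 14 without OMP_IGF1R 12. Without OMP_IGF1R 18 it was 21, while 569 of 17505 tested genes were called in all. That is an excess in the window (Fisher's exact test, two-sided, p = 0.00426). No other fit that left out 1 library gave a Fisher p under 0.05.

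The authors' deposited table gave 2123 genes at an adjusted p under 0.05, 783 with a positive and 1340 with a negative fold change. In the authors' deposited table Omp had a log2 fold change of -1.28 and Igf1r of -0.58, so its sign is that of the libraries titled OMP_IGF1R over those titled IGF1R_flfl. Of the 1425 edgeR calls, 1366 were called in the authors' deposited table in the same direction and 0 in the opposite direction, while 59 were called by edgeR alone and 756 tested genes by the authors alone. Chi3l4, the largest rise, was not called in the authors' deposited table (log2 0.22, adjusted p = 0.0988). DESeq2, run here on the same counts, did call it, with a log2 fold change of 5.99. Every gene named for its size changed less in the authors' deposited table than by edgeR. Examples are Fcgbp (0.99 against 3.03), Gm10935 (1.29 against 3.40) and Olfr297 (-1.34 against -2.46). The cause was not tested, so sizes cannot be compared directly between the 2. Fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.79 across genes, which are not independent replicates. Because large changes differ in size between them, this r does not measure whether they differ in direction or in calls.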

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

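The tests of dilution, of batches by title number, of Omp and of the genotype field, and the set of libraries left out together, were chosen after the results had been seen. Of 150 groups of 4 libraries checked for a library far from the other 3, 14 had one, where chance gives about 7.5.

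IGF1R_flfl 13 stood apart in Chi3l4 (48.2 CPM, against 0.305 to 4.997 CPM), in Fcgbp (42.1 CPM, against 15.8 to 19.8 CPM), in summed neutrophil genes (940 CPM, against 142.6 to 264 CPM) and in summed unfolded protein response genes (4567 CPM, against 4207 to 4212 CPM). OMP_IGF1R 17 stood apart in Myot (7.61 CPM, against 1.43 to 2.30 CPM), Clca2 (19.6 CPM, against 9.83 to 10.9 CPM), summed neutrophil genes (622.9 CPM, against 286.4 to 337.5 CPM) and summed skeletal muscle genes (403.4 CPM, against 19.97 to 27.19 CPM). Krt4, a keratin of squamous epithelium singled out after its values were seen, was at 205 CPM in that library. The neutrophil list shares Ltf with the gland and respiratory lists. Summed gland genes were also highest of their groups in IGF1R_flfl 13 (73230 CPM) and OMP_IGF1R 17 (63975 CPM). The neutrophil sums were thus not told apart from gland content. IGF1R_flfl 2 stood apart in summed bulb and oligodendrocyte genes (2825 CPM, against 984.9 to 1093 CPM) and in summed T and NK cell genes (69.27 CPM, against 10.31 to 20.17 CPM). Mbp, a myelin protein singled out after its values were seen, was at 1003 CPM in that library. Myot was at 1.12 CPM in IGF1R_flfl 1, against 0.686 to 0.753 CPM. Summed activity-linked genes were at 2728 CPM in OMP_IGF1R 12, against 2086 to 2153 CPM, and summed macrophage genes at 552.8 CPM in OMP_IGF1R 11, against 650.2 to 658 CPM. Summed bone and cartilage genes were at 413.3 CPM in IGF1R_flfl 3, against 569.9 to 600.4 CPM.

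Mature neuron and receptor genes were lower and immature neuron, precursor and cell cycle genes higher in the libraries titled OMP_IGF1R. Fewer neurons among otherwise like cells would raise progenitor and sustentacular genes alike. Instead the progenitor list moved 0.657 further than the sustentacular list on the log2 scale (exact permutation test, two-sided, n = 4 each, p = 0.0286, the smallest possible). Both list changes were known when this contrast was chosen, so it describes how they differ and its p is no separate support. Bulb tissue in IGF1R_flfl 2 does not account for the pattern. Without that library 166 of 191 called genes of the mature neuron, receptor, precursor and cell cycle lists (86.9%) kept call and direction. A batch that follows the numbers that open the titles (35138 to 35141 for IGF1R_flfl, 35156 to 35159 for OMP_IGF1R; not the replicate numbers) stays open, because all 8 libraries lie in their own group's range and the 2 cannot be told apart. A biological difference between the genotypes also stays open and was not tested.

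The genotype field and the titles disagree, and Igf1r and Omp were lower in the libraries whose genotype field names the control. All 4 libraries titled OMP_IGF1R lay below every library titled IGF1R_flfl in both genes. A genotype field exchanged between the groups would give this, but it restates what was seen, so an exchange stays open. Scaled to mature neuron genes Igf1r was no longer called (-0.12, edgeR adjusted p = 0.41). A prediction of the exchange, written after the results were seen, was that this call would stay, and it did not. The Igf1r fall was thus not told apart from that of the mature neuron list (median -0.53 before scaling). That scaling also moves the median of all genes from -0.012 to 0.52, and whole-gene counts do not measure a deletion. The lost call therefore does not decide the exchange. In both genes 0 libraries lay on the side of the other title group, which argues against 1 or 2 single mislabelled libraries. With libraries scaled to the other mature neuron genes Omp changed by -0.91 (SE 0.0803). That lies 2.88 SD below the mean of the 28 others and outside their range (-0.50 to 1.03, SD 0.315), so Omp fell further than they did. Members also expressed in other cells would fall less than Omp under a loss of mature neurons alone, and this was not separated. Such a loss as the whole cause therefore stays open. The range is wide, and Camk2b of the odour transduction list, chosen after its values were seen, lay lower still (-1.15). The Omp value lies 1.16 SE from -1, as a knock-in driver that replaces 1 of the 2 Omp copies would give, a hypothesis that genotypes or reads per allele, not analysed here, would decide. The values were not used to reassign any library.

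The 8 libraries can be parted into 4 and 4 in 35 ways. For called genes, 1 of the 35 splits, the real one, gave as many as 1425, and the highest other gave 3. Every other split mixes the title groups, so a difference between them widens its spread and lowers its count. With 35 splits the real one cannot rank rarer than 1 of 35, so chance is made less likely but is not excluded. For called receptors, 1 of the 35 gave 127 and the highest other 0, and near Omp and Igf1r 1 of the 35 gave 28 and the highest other 0. No other split called more than 3 genes in all, so these counts repeat the first and say nothing particular to receptors or the window. The share called near Omp and Igf1r was 8.54%, against 8.18% elsewhere (Fisher's exact test, two-sided, p = 0.76, and p = 0.00426 without OMP_IGF1R 18). For lists called by camera, 8 of the 35 gave 23 or more, the highest other 33, so chance is not excluded for the number of lists.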

How the results depend on the processing

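No paired analysis was possible because the groups share no replicate numbers. Leaving out both IGF1R_flfl 2 and OMP_IGF1R 17 was the one alternative chosen after seeing the data. After the first results had been seen, the genes followed through the alternatives were narrowed to those of the lists discussed, and the direction of a list was changed from that given by camera to the sign of its median. With DESeq2 size factors, upper-quartile factors, either filter, limma voom and that pair left out, the called genes numbered 1201 to 1850, and no gene called at first was called in the opposite direction. Upper-quartile factors gave 44.4% higher calls, against 34.5%. DESeq2 gave 2122 calls, 782 of them higher, and 45 genes near Omp and Igf1r. On simulated data 21.9% of its calls were false. There 200 of 17381 genes were changed, far fewer than were called here, so that share need not hold for these calls. Scaling to mature neuron genes gave 13145 calls (13012 higher, 133 lower), 166 near Omp and Igf1r, 58 receptors lower and an Igf1r change of -0.12, because it moves the median of all genes from -0.012 to 0.52, and 616 of the 1425 calls kept their direction while 226 were called in the opposite one. It turned the sign of Pcp4l1 (0.038), Kirrel3 (0.11), Eno1 (0.14), Gpi1 (0.25), Pfkp (0.26), Foxo3 (0.30), Slc17a6 (0.027), Syt1 (0.00188), Eomes (0.040), Cdhr1 (0.22), Gstm1 (0.18), Gclc (0.35), Cyp2a4 (0.038), Sult1d1 (0.21) and Sec14l3 (0.36), and of the list medians of mature neurons (0.00188), odour transduction (0.022), activity-linked genes (0.21), sustentacular cells (0.51), glands (0.42), respiratory cells (0.38), red blood cells (0.44), glycolysis (0.35), olfactory receptors (0.20), trace amine receptors (0.060), axon guidance (0.39), heat shock (0.49), the mitochondrial genome (0.28) and the respiratory chain (0.43); these follow from the shift of all genes, and for mature neurons the scaling sets them. Of the 23 camera calls, 9 were kept in the same direction under it and 14 were lost. The gland median (-0.02) also turned with upper-quartile factors (0.0077), no filter (0.091), the filter of 1 CPM (0.093) and voom (0.17), and without IGF1R_flfl 1 (0.13) or 13 (0.39) or OMP_IGF1R 11 (0.15), 12 (0.16) or 18 (0.14), within a range of -0.68 to 0.39 over the libraries left out; the cause was not tested. Lists called numbered 0 with an estimated correlation and 8 by fry, and a window of 5 Mb held 10 called genes. Leaving out 1 library gave 569 to 1477 called genes, 189 to 513 higher, 380 to 964 lower, 54 to 124 receptors, 14 to 25 genes near Omp and Igf1r, 20 to 28 lists, 11 to 15 separated sums, and changes of -0.75 to -0.57 for Igf1r and -1.52 to -1.32 for Omp, both called each time; the lowest count, 569, was without OMP_IGF1R 18, and 1 fewer library also lowers power. Genes at a few reads per library are limited by depth.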

Other observations

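The tests on Alb were chosen after its values had been seen, except that of the sum of all other liver genes.

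Genes of microvillar and tuft-like cells, chemosensory cells of the epithelium, were higher in the libraries titled OMP_IGF1R. Of 22 tested members, 7 rose and 0 fell (median log2 0.50), and 11 rose adjusted over the list alone. They included Alox5 (1.01), the enzyme that starts leukotriene synthesis, Avil (1.17), an actin-binding protein, the cation channel Trpm5 (0.93), and Sh2d6 (1.21). Their summed expression was 818 ± 69.98 and 1045 ± 119 CPM, with no overlap (exact permutation test, two-sided, n = 4 each, p = 0.0286, adjusted p = 0.119). The gap was narrow: OMP_IGF1R 17 stood at 878.2 CPM, and IGF1R_flfl 1 and 13 at 877.4 and 876.1 CPM. Camera called the list (adjusted p = 4.40e-10, and adjusted p = 0.30 with an estimated correlation), and without IGF1R_flfl 2 and OMP_IGF1R 17 there were 8 higher genes.

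Interferon and inflammation lists leaned higher with few called members. In the interferon list 2 of 31 rose, Mx1 (1.21) and Oasl1 (1.06, call lost without any 1 library but IGF1R_flfl 1, adjusted p up to 0.101), and Oas1a (0.86) and Ifi44 (0.89) did not pass. In the inflammation list 2 of 20 rose, Il1rn (1.81) and Lcn2 (1.19), whose calls were lost without any 1 library but IGF1R_flfl 13 for Il1rn (adjusted p up to 0.0826) and but IGF1R_flfl 2 or OMP_IGF1R 12 for Lcn2 (up to 0.0971). Mx1 lost its call without IGF1R_flfl 1 or 3 or OMP_IGF1R 12 or 18 (up to 0.0723). Adjusted over the list alone, 2 rose in each. Their summed expression overlapped between the groups: 406 ± 35.1 and 496 ± 121 CPM for interferon genes, the highest in OMP_IGF1R 17 (662 CPM), and 494 ± 18.9 and 532 ± 54.6 CPM for inflammation genes (exact permutation tests, two-sided, n = 4 each, p = 0.229 and 0.286). Camera gave adjusted p = 1.35e-06 and 0.00037, lost with an estimated correlation (adjusted p = 0.57 and 0.40) and with libraries scaled to mature neuron genes (adjusted p = 0.41 and 0.89). In the circadian clock list Per3 rose (0.40, also adjusted over the list alone), and its call was lost without OMP_IGF1R 12 or 18 (adjusted p up to 0.0566). Camera gave that list an adjusted p = 0.0247, adjusted p = 0.51 with an estimated correlation and adjusted p = 0.0755 under that scaling.

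Activity-linked genes of sensory neurons were lower in 5 of 12 cases (6 adjusted over the list alone): Pcp4l1 (-0.50), Srxn1 (-0.67), Kirrel3 (-0.43), Rasgrp4 (-0.58) and, named after its values were seen, Sema7a (-0.45). Kirrel3 lost its call without IGF1R_flfl 13 or 3 or OMP_IGF1R 12, 17 or 18 (adjusted p up to 0.101), and Rasgrp4 without IGF1R_flfl 13 or 3 or OMP_IGF1R 11, 17 or 18 (up to 0.0869). Camera gave an adjusted p = 0.0102 (0.40 as adjusted p with an estimated correlation). With libraries scaled to mature neuron genes, which moves all genes up, the list median was 0.21, Pcp4l1 0.038 and Kirrel3 0.11. Camera placed the list lower than other genes (adjusted p = 0.000226), but the scaling is set by genes of the same neurons, so this is no separate support. In glycolysis 2 of 22 fell, Pgam1 (-0.57) and Eno1 (-0.40, lost without any 1 library but IGF1R_flfl 2 or OMP_IGF1R 17, adjusted p up to 0.134), 4 adjusted over the list alone, with a camera adjusted p = 0.00656 and adjusted p = 0.51 with an estimated correlation. Of 83 ribosomal protein genes 0 were called by edgeR (median log2 0.11, camera adjusted p = 1.06e-09, and adjusted p = 0.57 with an estimated correlation), and of 87 nuclear respiratory chain genes 1 fell (median -0.10, camera adjusted p = 0.000152, and adjusted p = 0.70 with an estimated correlation). Under that scaling camera no longer called the glycolysis and respiratory chain lists (adjusted p = 0.41 and 0.0815), whose medians moved up with all genes, to 0.35 and 0.43. For the ribosomal genes, 24 had an unadjusted edgeR p under 0.05, DESeq2 called 16 and voom 0.

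Other lists called by camera had few called members. The FOXO-linked list had 2 of 21 higher and 2 lower (adjusted p = 0.0326, 0.41 as adjusted p with an estimated correlation), B and plasma cells 1 of 11 higher (0.00954, and 0.51), and T and NK cells 0 of 12 (0.00273, and 0.51). Macrophages had 0 of 20 (0.00311, and 0.70), MHC class II 0 of 10 (0.0137, and 0.57), fibrous matrix 0 of 18 (0.0201, and 0.70) and endothelium and pericytes 0 of 18 (0.0328, and 0.70). In these, the first value in parentheses is the camera adjusted p and the second the adjusted p with an estimated correlation, and with libraries scaled to mature neuron genes camera called 0 of them (adjusted p of 0.0581 to 0.96). The lists not called by camera were respiratory cells (2 of 23 lower, adjusted p = 0.197), ensheathing glia (0 of 17, 0.24), neutrophils (2 higher and 1 lower of 13, 0.231), red blood cells (0 of 7, 0.92), bone and cartilage (0 of 18, 0.151), vomeronasal neurons (1 of 9 lower, 0.67), guanylyl cyclase D neurons (0 of 7, 0.0619), axon guidance (2 higher and 3 lower of 27, 0.0881), cholesterol synthesis (0 of 24, 0.38), lipid storage (0 of 22, 0.29), unfolded protein response (0 of 26, 0.38), heat shock (0 of 17, 0.28), oxidative stress (3 of 26 lower, 0.67), apoptosis (3 higher and 1 lower of 28, 0.116), immediate early genes (1 of 21 higher, 0.0531), hormone receptors (1 of 13 lower, 0.38), trace amine receptors (1 of 11 lower, 0.0619) and the mitochondrial genome (0 of 10, 0.101). Vomeronasal receptors had 1 gene tested and no list test. Over the 19 lists with 0 edgeR calls, ribosomal, muscle, gland and sustentacular genes included, 74 members had an unadjusted edgeR p under 0.05, DESeq2 called 34 and voom 5.

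Alb, the liver's albumin, was singled out after its values were seen, since it lies under the expression limit for named genes. It had 0 counts in each of the 4 libraries titled IGF1R_flfl and 47, 62, 46 and 41 counts in OMP_IGF1R 11, 12, 17 and 18 (2.09 ± 0.376 CPM, n = 4), which is at least 70.3-fold higher against a floor of 3 counts over the group. Liver RNA, or reads crossing over from a liver library, could add other liver genes. Their summed CPM was higher by 12.9, above the Alb level of 2.09 that had been asked for beforehand, but the groups overlapped (exact permutation test, two-sided, n = 4 each, p = 0.77), and Apoc1 and Cyp2e1 make up most of that sum in both groups. Without these 2 the sum was 3.08 ± 0.608 and 5.80 ± 0.923 CPM, higher by 2.72 with no overlap (exact permutation test, two-sided, n = 4 each, p = 0.0286, the smallest possible). Of the 25 other liver genes, 17 had more counts in the libraries titled OMP_IGF1R, 5 fewer and 3 as many. Among those singled out after their values were seen, Ahsg had 119 and 200 counts, Apob 6 and 41 and Fabp1 0 and 13, while Apoa1 had 14 and 9 and Apoc3 0 in both. Such RNA or reads are thus a candidate source, as a hypothesis. A batch that follows the numbers that open the titles cannot be told apart from the group, since Alb places all 8 libraries with their number range, and no biological explanation was tested.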
